A study of Homo sapiens with 12 samples.

How the data were processed

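Messenger RNA was sequenced from cultured human neuroblastoma cells in 12 libraries. The labels place them in 4 groups of 3 libraries: SK-N-AS control, SK-N-AS with ML210, SK-N-BE(2) control and SK-N-BE(2) with ML210. The group and the replicate number come from each sample's title, and a batch label from 1 to 3 equals the replicate number in every library. Per the labels' protocols, RNA was extracted with a column kit and made into stranded mRNA libraries for an Illumina NovaSeq instrument.

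The deposited values were counts per gene, whole numbers that had not been normalized. Per the submitters' processing notes, the tools named were FastQC, Trimmomatic (given as 1.4), HISAT2 2.2.1 and featureCounts 2.0.5, with the builds GRCh38 and hg38. The strand setting, the treatment of multi-mapping reads, the gene annotation and whether reads or read pairs were counted are not given in the sources used here. Reads of a gene and an overlapping antisense gene, as for MYCN and MYCNOS, may therefore be mixed in these counts. Values of genes that share sequence with near-identical copies are uncertain for the same reason, which concerns TRIM16 and TRIM16L, the MT1 metallothioneins, the ferritins FTH1 and FTL, the alpha-tubulin TUBA4A, HSPA1A and HSPA1B, and the histones.

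The table held 61552 genes, of which 36967 had at least 1 read in some library. Gene symbols came from a separate reference of gene names for 61399 identifiers, 145 more were named from GENCODE release 29 on GRCh38, and 8 had no name. Coordinates are those of GENCODE release 29. Library totals lay between 54047293 and 83481963 counted reads. Intervals and floors cover counting error only, and a floor of 3 reads was used.

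Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 20304 genes, and libraries were scaled by TMM. CPM values were computed by edgeR from the TMM-scaled library totals. All 12 libraries entered 1 fit with a coefficient per group (8 residual degrees of freedom, common dispersion 0.0223), so that all comparisons shared an estimate of the spread. Each comparison was tested with the robust edgeR quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p of single genes in the text are from this test unless another is named. The comparisons were ML210 minus control within each line label, the difference of these responses (labelled SK-N-BE(2) minus labelled SK-N-AS), and control labelled SK-N-BE(2) minus control labelled SK-N-AS.

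The lists of genes, 30 in number with 719 members, were fixed before the data were examined, together with the groups, the comparisons, the tests, the alternatives to these tests and the rule for naming genes. Of the members, 718 were matched to an identifier. Some genes belong to several lists, so called members of different lists need not be different genes. Lists with at least 5 tested members, 29 in all, were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list call is given beside the adjusted p of camera with the correlation estimated per list. Counts of called members are given over all genes and adjusted over the list alone. The lists of mitochondrially encoded transcripts, ribosomal proteins and histones were fixed as checks on RNA quality and selection. Whether the make-up of the libraries rather than the cells moved these lists was not tested. The rotation test fry was an alternative. It asks whether members move, on balance, in 1 direction and does not compare a list with other genes.

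The naming rule took GPX4 and MYCN first. For each ML210 comparison it then took up to 8 protein-coding genes each way with the largest fold change among called genes with a mean log2 CPM of at least 2 and the same direction in all 3 same-batch pairs. For the difference of the responses it took 6 each way, and for the controls 8 each way. It added up to 4 members with the smallest adjusted p for each list with called members, and for ferroptosis suppressors and promoters any member needed to state the count. Genes named outside this rule are said to have been chosen after their values were seen. The inactivation marker XIST, its antisense partner and Y-linked genes were left out.

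Because the batch label is shared, same-numbered libraries were treated as paired in the naming rule and in the fits with a replicate block. The correlation of deviations from the group means for same-batch control and ML210 libraries was 0.357, 0.068 and 0.121 for batches 1, 2 and 3 labelled SK-N-AS, and 0.096, 0.12 and 0.169 for those labelled SK-N-BE(2). Between the controls of both line labels it was -0.082, -0.003 and -0.027. For control and ML210 libraries of different batches it lay from -0.269 to 0.189 labelled SK-N-AS and from -0.1 to -0.007 labelled SK-N-BE(2). AS control 2 was closer to AS ML210 3 (0.189) than to AS ML210 2, and AS control 3 to AS ML210 2 (0.125) than to AS ML210 3. These values do not favour the pairing of batches 2 and 3 in that label. The fit had no batch term, as chosen before the data were examined. Fits with a replicate block, either common to both lines or within each line, were alternatives, and the pairing rests on the batch label. In the libraries labelled SK-N-AS alone, batch in the model lowered the common dispersion from 0.0218 to 0.00775. In those labelled SK-N-BE(2) alone it fell from 0.0227 to 0.0091. Spread between batches within a line was therefore part of the error in the fit without a batch term. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 11.45 and 61.58, so none was counted as a copy of another.

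The test was checked on simulated counts drawn from the real means and library sizes, with a seeded set of genes changed. For ML210 labelled SK-N-AS, over 19868 genes, it recovered 55.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false among 166 calls. For ML210 labelled SK-N-BE(2), over 19845 genes, these shares were 46.3%, 89.6% and 92.4%, with 8 false among 160 calls. The difference of the responses recovered 34.3%, 67.2% and 87.9% of changes placed in the libraries labelled SK-N-AS, and 29.9%, 62.7% and 89.4% of those placed in the libraries labelled SK-N-BE(2). The set test called 0 of 29 unchanged lists in either simulation, which was made of independently drawn genes. Genes to change were taken only from those with high mean counts. Each gene had the same spread in all groups, and there was no batch effect. The shares recovered therefore need not hold for genes with low counts or with a spread that differs between groups.

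Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, a looser and a stricter filter on low counts, glmTreat against a fold of 1.5, each line fitted alone, replicate blocks and leaving out each library in turn. No column of values was left out.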

Results

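Gene expression was measured by mRNA sequencing in cultured human neuroblastoma cells kept overnight with or without ML210. ML210 is a covalent inhibitor of GPX4, the selenoenzyme that reduces lipid peroxides in membranes, and induces ferroptosis, an iron-dependent form of cell death. The series compares SK-N-BE(2), which its design calls MYCN-amplified, with SK-N-AS, which it calls non-amplified, and so asks how neuroblastoma lines of either MYCN status respond to GPX4 inhibition. There is 1 line of each status, so line and MYCN status cannot be told apart. Each of the 4 groups held 3 libraries, 1 from each of 3 batches. Nothing beyond the batch label states that they came from separate cultures, so p-values measure only the spread between these libraries. The counted reads were 83481963, 68868770 and 70653713 for SK-N-AS control replicates 1, 2 and 3, and 54047293, 72626480 and 66122193 for SK-N-AS ML210. They were 57990008, 67177805 and 65578851 for SK-N-BE(2) control and 60574810, 58115886 and 64926300 for SK-N-BE(2) ML210. The line label separated the libraries along a principal component that held 86.5% of the variance. Libraries are named by label throughout, so that AS control 2 is the control library labelled SK-N-AS, replicate 2, and BE(2) ML210 3 the ML210 library labelled SK-N-BE(2), replicate 3.

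MYCN, the transcription factor whose amplification defines the contrast between the lines, went against the line labels in all 12 libraries. MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007 on GRCh38) stood at 3558 ± 122 CPM (SD, n = 3) in the controls labelled SK-N-AS and at 3855 ± 115 CPM in their ML210 libraries. In the libraries labelled SK-N-BE(2) it stood at 0.166 ± 0.0727 CPM in controls and 0.154 ± 0.0899 CPM with ML210, from 34 and 31 reads per group against 719480 and 700195. The log2 difference between the controls was -14.38 (SE 0.214, edgeR quasi-likelihood adjusted p = 9.32e-14). The labels were kept as given, and each direction between the lines is one between labels that MYCN contradicts. GPX4 (ENSG00000167468, chromosome 19, 1103926 to 1106791) did not pass the test in any comparison. Its level was 269.5 ± 11.2 CPM in controls and 248.4 ± 4.88 CPM with ML210 labelled SK-N-AS (log2 -0.12, adjusted p = 0.751), and 246.8 ± 9.23 and 234.3 ± 17.1 CPM labelled SK-N-BE(2) (log2 -0.08, adjusted p = 0.667). The difference of the GPX4 responses was 0.04 (adjusted p = 0.969), and the controls differed by -0.13 (adjusted p = 0.071).

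**Figure D1:**
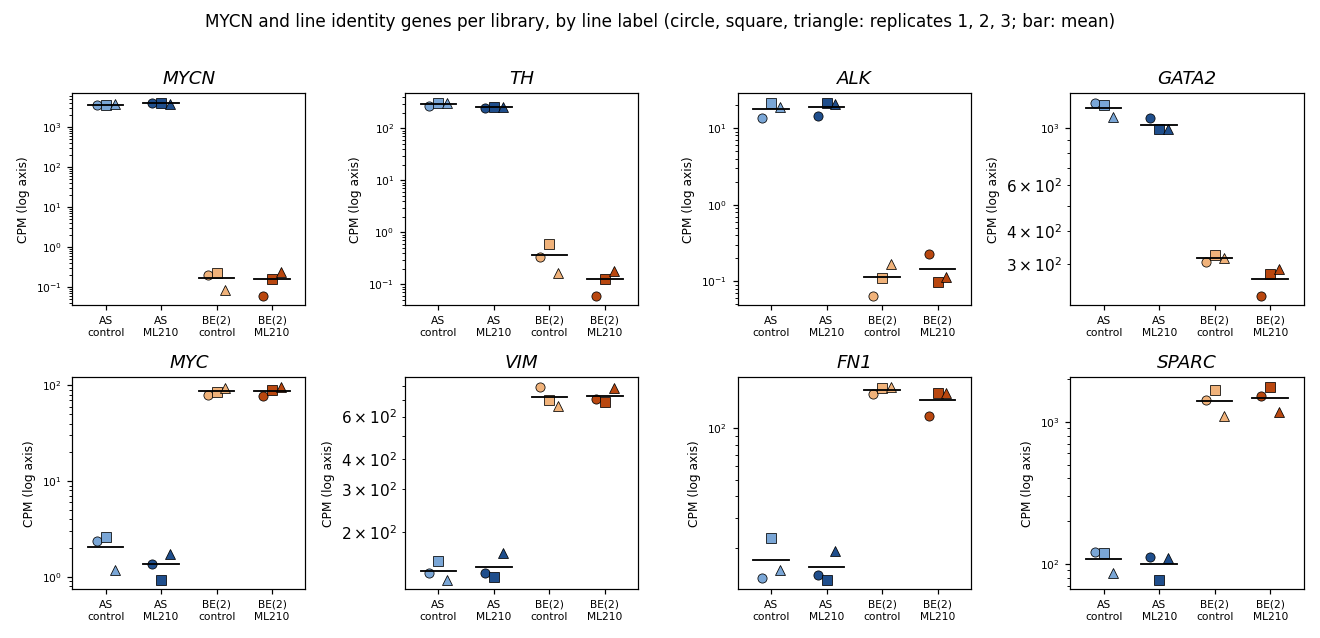
CPM on a log axis for MYCN, adrenergic genes (TH, ALK, GATA2), MYC and mesenchymal genes (VIM, FN1, SPARC) in each of the 12 libraries by line label and treatment, with replicates as symbols and group means as bars. MYCN lies above 3000 CPM in the 6 libraries labelled SK-N-AS and below 1 CPM in the 6 labelled SK-N-BE(2).

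The controls of the 2 line labels differed in most genes, with adrenergic genes lower and mesenchymal, cytokine and interferon genes higher in the libraries labelled SK-N-BE(2). These list calls were lost with an estimated correlation (adjusted p = 0.748, or 0.492 for interferon genes). The directions given here are by label, and MYCN runs opposite to those labels. Beside MYCN, the largest differences toward the label SK-N-AS among protein-coding genes with a mean log2 CPM of at least 2 and 1 direction in all same-batch pairs were in the synaptic complexin CPLX2 (log2 -11.27), the caytaxin gene ATCAY (-10.74), the axonal kinesin KIF1A (-10.38), the endosomal neuronal gene NSG2 (-10.38), the Notch ligand relative DLK1 (-10.08), tyrosine hydroxylase TH (-9.60) and the RNA-binding protein gene IGF2BP1 (-9.20). TH stood at 291.8 CPM in the controls labelled SK-N-AS and 0.372 CPM in those labelled SK-N-BE(2). The largest toward the label SK-N-BE(2) within the same limits were PTPRC, which encodes the phosphatase CD45 (8.27, from 0.987 to 289.9 CPM), and the mesenchymal homeobox gene PRRX1 (8.09). Both rest on traces in the controls labelled SK-N-AS, with PTPRC at 0, 1.634 and 1.327 CPM and PRRX1 at 0.026, 1.538 and 1.39 CPM in replicates 1, 2 and 3. Within the same limits on CPM and direction, PTPRC and PRRX1 were followed by the membrane proteins VAT1L (7.84) and TMEM176A (7.83) and the antiviral IFITM3 (7.78). Next were the ephrin receptor EPHA7 (7.53), the exporter ABCC2 (7.49) and the oncostatin M receptor OSMR (7.38). Of protein-coding genes at 50 CPM or more in every library labelled SK-N-BE(2) and under 3% of that level in every library labelled SK-N-AS, 42 were found, a set chosen after values were seen. Their median level, relative to the mean labelled SK-N-BE(2), was 0.346, 1.69 and 1.48% in AS control 1, 2 and 3 and 0.362, 1.19 and 1.77% in AS ML210 1, 2 and 3. The lowest of the 42 stood at 0, 0.649 and 0.527% and at 0, 0.365 and 0.614%, so folds of such genes are uncertain. In the reverse direction 69 genes had medians of 0.364, 0.256 and 0.525% in BE(2) control 1, 2 and 3 and 0.362, 0.315 and 0.446% in BE(2) ML210 1, 2 and 3, with the lowest at 0 in each, and folds such as those of CPLX2, ATCAY and TH rest on such traces. Over all genes, 6893 were higher and 7154 lower in the controls labelled SK-N-BE(2), which is 49.1% higher. With library totals in place of TMM the split was 8575 higher and 5550 lower, which is 60.7% higher, and the median log2 difference of all genes moved from -0.005 to 0.243.

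Of 25 tested genes of adrenergic neuroblastoma identity, 21 were lower and 3 higher in the controls labelled SK-N-BE(2) (median log2 -2.28, camera adjusted p = 0.000307, adjusted p = 0.748 with an estimated correlation). They included the receptor kinase ALK (-7.24), the growth cone protein GAP43 (-4.39) and the transcription factor GATA2 (-1.91). Of 24 mesenchymal identity genes, 17 were higher and 1 lower (median 3.58, adjusted p = 0.00115, adjusted p = 0.748 with an estimated correlation), among them SPARC (3.69), fibronectin FN1 (3.32), vimentin VIM (2.39) and TGFBR2 (1.76). NF-kB and cytokine targets had 17 of 19 higher and 1 lower (median 3.46, adjusted p = 0.000307, adjusted p = 0.748 with an estimated correlation), with the adhesion molecule ICAM1 at 7.92 and TNFAIP2 at 4.74. Interferon-stimulated genes had 17 of 21 higher and 2 lower (median 2.16, adjusted p = 0.00033, adjusted p = 0.492 with an estimated correlation), with RSAD2 at 4.45, IFIT3 at 2.49 and OAS3 at -1.04. Counts adjusted over the list alone were equal to these, except for 4 adrenergic genes higher.

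Lists of growth and respiration were lower in the controls labelled SK-N-BE(2). The nuclear-encoded respiratory chain had 21 of 28 members lower (18 lower and 5 higher with library totals, median -0.83, adjusted p = 0.00017, adjusted p = 0.748 with an estimated correlation), including COX4I1 (-1.64) and ATP5PB (-1.55). ATF4 targets of the integrated stress response had 27 of 37 lower and 4 higher (median -0.93, adjusted p = 0.00032, adjusted p = 0.748 with an estimated correlation), with the serine synthesis enzyme PSAT1 at -2.31 and the folate enzyme ALDH1L2 at -7.76. Proliferation genes had 24 of 32 lower and 4 higher (median -0.71, adjusted p = 0.00062, adjusted p = 0.748 with an estimated correlation), including the replication factors GINS2 (-3.23) and MCM5 (-2.03), while cyclin E1 CCNE1 was higher (1.93). Mitochondrially encoded transcripts had 11 of 13 lower and 1 higher (median -1.55, adjusted p = 0.00319, adjusted p = 0.748 with an estimated correlation), with MT-CO1 at -1.96. Targets of MYC and MYCN had 21 of 30 lower and 6 higher (median -0.50, adjusted p = 0.00365, adjusted p = 0.748 with an estimated correlation), among them the polyamine enzyme ODC1 (-1.76) and nucleolin NCL (-1.11), while MYC itself, read as an immediate early gene, was higher (5.38). Cytosolic ribosomal proteins had 25 of 35 lower and 5 higher (14 lower and 9 higher with library totals, median -0.33, or -0.08 with library totals, adjusted p = 0.00535, adjusted p = 0.748 with an estimated correlation), with RPS3 at -1.64 and RPL8 at 1.05. Counts adjusted over the list alone were the same for these 6 lists. With library totals the medians were -0.68 for ATF4 targets (23 lower, 4 higher), -0.46 for proliferation (21 lower, 8 higher), -1.30 for mitochondrially encoded transcripts (10 lower, 1 higher) and -0.25 for targets of MYC and MYCN (17 lower, 7 higher).

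The other lists were not called between the controls, although single members were far apart. In the NRF2 list 15 of 33 were higher and 10 lower (adjusted p = 0.424), with the quinone reductase NQO1 at 2.56. Among ferroptosis suppressors 8 of 24 were higher and 10 lower (adjusted p = 0.909), with NFE2L2, which encodes NRF2, at 1.09 and the acyltransferase MBOAT1 at 5.52. Among ferroptosis promoters 6 of 23 were higher and 12 lower (adjusted p = 0.419), with ACSL4, which activates polyunsaturated fatty acids for membrane lipids, at -0.70. Glutathione genes had 7 of 27 higher and 14 lower (adjusted p = 0.424), with the transferase GSTP1 at -3.94. Hypoxia targets had 7 of 22 higher and 6 lower (adjusted p = 0.953), with lactate dehydrogenase LDHA at 4.74, from 46.95 to 1254 CPM. As markers of other cells, the endothelial list had 1 of 10 higher and 7 lower (adjusted p = 0.111). The epithelial list had 4 of 8 higher and 2 lower (adjusted p = 0.429), with the keratins KRT18 at 6.25 and KRT8 at 6.09. The Schwann cell list had 4 of 8 higher and 3 lower (adjusted p = 0.909; median 0.31 but mean -0.77). In the Schwann list S100B had 3 reads in the controls labelled SK-N-BE(2) against 745, a ratio of 252 with a counting interval of 86.3 to 1220. Blood markers had 3 tested members, too few for the set test: PTPRC and CSF1R (1.53) were higher and CD14 (-2.17) lower. CSF1R was not called without AS control 3 (adjusted p = 0.0637) or without BE(2) control 1 (0.0982).

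The remaining adjusted p between the controls were 0.107 for replication-dependent histones, 0.124 for cholesterol synthesis, 0.27 for both the heat shock response and lysosome genes, 0.334 for metallothioneins, 0.369 for the unfolded protein response, 0.419 for iron handling, 0.493 for fatty acid synthesis and for p53 targets, 0.539 for selenoproteins and 0.909 for immediate early genes. Median and mean had opposite signs for selenoproteins (-0.28 and 0.02), ferroptosis suppressors (-0.14 and 0.08), ferroptosis promoters (-0.42 and 0.14), iron handling (-0.28 and 0.08), immediate early genes (-0.06 and 0.11) and hypoxia targets (-0.07 and 0.03, tested direction up). Adjusted over the list alone, 7 promoters were higher and 15 glutathione genes lower, with the other counts unchanged. With library totals in place of TMM the medians of the unfolded protein response, heat shock, ferroptosis suppressor, glutathione, cholesterol, immediate early and hypoxia lists turned from negative to positive. The members higher and lower were then 9 and 8, 8 and 8, 10 and 5, 10 and 7, 11 and 9, 11 and 10, and 10 and 5, in that order. The same scaling gave 18 and 6 for NRF2 targets, 16 and 6 for p53 targets, 11 and 11 for iron handling, 7 and 10 for ferroptosis promoters, 7 and 6 for selenoproteins, 8 and 9 for fatty acid synthesis, 8 and 11 for lysosome genes, 4 and 0 for metallothioneins and 9 and 1 for histones.

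In the libraries labelled SK-N-AS, ML210 raised 5 genes and lowered 1 of 20304 past the threshold. NQO1, a quinone reductase and classical NRF2 target, rose from 33.3 ± 2.95 to 62.0 ± 2.79 CPM (SD, n = 3; log2 0.90, SE 0.0849, adjusted p = 0.000711). CPT1A, which carries long-chain fatty acids into mitochondria, rose from 34.4 ± 3.98 to 59.9 ± 1.94 CPM (0.80, SE 0.0749, adjusted p = 0.000711). The tripartite-motif gene TRIM16L rose by 1.14 (adjusted p = 0.00296), the iron-binding protein gene PIR by 0.61 (adjusted p = 0.0188) and the metallothionein MT1X from 1.29 ± 0.309 to 4.36 ± 1.17 CPM (log2 1.75, adjusted p = 0.0188). HR, which encodes the hairless corepressor, fell from 39.98 ± 4.03 to 19.81 ± 2.65 CPM (log2 -1.01, SE 0.14, adjusted p = 0.0188). All 6 moved the same way in 3 of 3 same-batch pairs, and 1398 genes had an unadjusted p under 0.05. Values of TRIM16L and MT1X are uncertain because their reads may be shared with close relatives.

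Of 33 tested NRF2 targets, 3 rose in these libraries and 30 did not pass the test, with 13 rising adjusted over the list alone (median log2 0.29, camera adjusted p = 4.04e-15, adjusted p = 0.328 with an estimated correlation). Metallothioneins, which bind zinc and copper, rose as a list (1 of 8 over all genes, 6 adjusted over the list alone, median 2.59, adjusted p = 5.13e-12, adjusted p = 0.0773 with an estimated correlation). Proliferation genes fell as a list (0 of 32 called, 8 adjusted over the list alone, median -0.15, adjusted p = 5.13e-12, adjusted p = 0.328 with an estimated correlation). Mitochondrially encoded transcripts, listed as a check on RNA quality, were also lower (0 of 13, 4 adjusted over the list alone, median -0.33, adjusted p = 5.95e-08, adjusted p = 0.333 with an estimated correlation). Their share of the reads was 4.86, 5.52 and 6.07% in the controls and 4.47, 4.21 and 5.15% with ML210. ATF4 targets rose (0 of 37, 5 adjusted over the list alone, median 0.14, adjusted p = 1.71e-06, adjusted p = 0.328 with an estimated correlation), and the nuclear-encoded respiratory chain fell (median -0.10, adjusted p = 2.29e-05, adjusted p = 0.506 with an estimated correlation). These 6 lists were called in every fit that left out 1 library. With a replicate block within each line, 7 NRF2 targets and 2 ATF4 targets rose, and 1 adrenergic and 1 fatty acid synthesis gene fell. The 1 glutathione gene and the 1 ferroptosis suppressor that rose were both GCLM, which is also among the 7 NRF2 targets.

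A further 7 lists were called with no member past the threshold, either over all genes or adjusted over the list alone, and each lost its call without some library. Immediate early genes fell (median -0.19, adjusted p = 0.00168, adjusted p = 0.328 with an estimated correlation; 0.0546 without AS control 2 and 0.0686 without AS ML210 2). The unfolded protein response rose (0.05, adjusted p = 0.00291, adjusted p = 0.531 with an estimated correlation; 0.0523 without AS control 2 and 0.0554 without AS ML210 1). Replication-dependent histones, whose mRNAs lack poly(A) tails and which were listed as a check on RNA selection, rose (0.30, adjusted p = 0.00671, adjusted p = 0.531 with an estimated correlation), with 0.129 without AS control 1, 0.087 without AS ML210 2 and 0.127 without AS ML210 3. Lysosome genes rose (0.07, adjusted p = 0.00768, adjusted p = 0.588 with an estimated correlation), with 0.122 without AS control 1 and 0.0599 without AS ML210 2. Interferon-stimulated genes fell (-0.28, adjusted p = 0.0117, adjusted p = 0.328 with an estimated correlation), with 0.13 without AS control 2 and 0.0686 without AS ML210 2. Glutathione genes rose (0.12, adjusted p = 0.0153, adjusted p = 0.328 with an estimated correlation), with 0.0681 without AS control 2 and 0.111 without AS ML210 1. Cholesterol synthesis genes fell (-0.10, adjusted p = 0.0349, adjusted p = 0.627 with an estimated correlation), with 0.0644 without AS control 2, 0.348 without AS control 3 and 0.477 without AS ML210 1. Fitted to these 6 libraries alone, cholesterol synthesis (0.0585) and interferon-stimulated genes (0.0629, or 0.0523 with a replicate block) lost their call and ferroptosis suppressors gained one (0.0466, higher).

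Of the lists that were not called in the libraries labelled SK-N-AS, targets of MYC and MYCN had an adjusted p of 0.0743 (0.0159 without AS control 2 and 0.00281 without AS ML210 1) and hypoxia targets 0.0991 (0.0252 with a replicate block within each line and 0.0497 with one in this line alone). Hypoxia targets were called lower without AS control 1 (1.69e-06), AS ML210 2 (0.0249) or AS ML210 3 (0.047). The mesenchymal list (0.697) and the endothelial list (0.697) were called without AS ML210 3, at 0.0163 and 0.0493. The others had an adjusted p of 0.211 for both ferroptosis suppressors and selenoproteins, 0.449 for ferroptosis promoters, 0.464 for Schwann cell markers and 0.513 for epithelial markers. It was 0.531 for ribosomal proteins, 0.532 for adrenergic genes (1 lower adjusted over the list alone), 0.546 for iron handling, 0.661 for heat shock and for p53 targets, 0.705 for fatty acid synthesis (median below 0, mean 0.04) and 0.925 for NF-kB targets (median 0.01, mean 0.27, tested direction down).

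The replicate block within each line gave 38 genes labelled SK-N-AS (21 higher, 17 lower), and the 6 libraries fitted alone gave 21 (15 higher, 6 lower). Genes added by the block, chosen after their values were seen, were the glutathione synthesis subunit GCLM (0.63), the glycine transporter SLC6A9 (0.83) and the sterol regulator SREBF1 (-0.32). RET, the receptor kinase for GDNF-family ligands, was also among them (-0.83, adjusted p = 0.000747 with the block and 0.398 without). Fitted alone, the heme oxygenase HMOX1 (1.83, adjusted p = 0.000485 against 0.576 in the shared fit) and the cystine transporter SLC7A11 (1.12, adjusted p = 0.00269 against 0.614) passed the threshold, as genes also chosen after their values were seen. Leaving out AS control 2 or AS ML210 2 left 3 genes each, NQO1, CPT1A and TRIM16L, which were called in all 6 fits without 1 library. HR was lost without AS control 2 (adjusted p = 0.168), AS control 3 (0.12), AS ML210 1 (0.128), AS ML210 2 (0.136) or AS ML210 3 (0.0521), and with a replicate block common to both lines (0.0849). PIR was lost without AS control 1 (0.0942), AS control 2 (0.15), AS ML210 2 (0.136) or AS ML210 3 (0.143), and MT1X without AS control 2 (0.0769), AS control 3 (0.0925), AS ML210 1 (0.0824) or AS ML210 2 (0.136).

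In the libraries labelled SK-N-BE(2), ML210 raised 166 genes and lowered 113, of which 65 changed at least 2-fold. Among protein-coding genes with a mean log2 CPM of at least 2 that moved alike in all same-batch pairs, the largest rise was in HMOX1, which degrades heme and releases iron, from 5.82 ± 0.645 to 76.4 ± 64.0 CPM (SD, n = 3; log2 3.72, SE 0.59, adjusted p = 0.0256). SLC7A11, the cystine importer that feeds glutathione synthesis, rose from 11.6 ± 1.18 to 46.8 ± 29.6 CPM (2.01, SE 0.376, adjusted p = 0.0377). The largest fall within the same limits was in RET, from 721.7 ± 91.8 to 242.4 ± 61.04 CPM (-1.57, SE 0.191, adjusted p = 0.00965). Further large rises were in TUBA4A (alpha-tubulin, 2.33), B4GALNT1 (the GM2 and GD2 ganglioside synthase, 2.07), KIF1A (1.70), PALM3 (a paralemmin, 1.68), FTL (ferritin light chain, 1.39) and RENBP (an aminosugar epimerase, 1.39). KIF1A (0.731 to 2.41 CPM) and RENBP (0.987 to 2.60 CPM) were low here and met the limit on CPM through their level labelled SK-N-AS, and KIF1A lay within the traces of that label. Further falls were in the serotonin receptor HTR2B (-1.20), the myosin MYH15 (-1.12), SMIM3 (-1.12), HR (-0.94), the metalloproteinase MMP28 (-0.94), the metalloproteinase inhibitor TIMP3 (-0.88) and CCDC33 (-0.83). These 16 genes moved the same way in 3 of 3 same-batch pairs, with adjusted p between 0.00965 and 0.0377.

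NRF2 targets held the most called members in the shared fit, while each line fitted alone called 4 of them labelled SK-N-BE(2) and 6 labelled SK-N-AS. Of 33 tested, 21 rose, 12 did not pass the test and none fell, with 30 rising adjusted over the list alone (median log2 0.88, camera adjusted p = 8.54e-33, adjusted p = 0.101 with an estimated correlation). Examples were TRIM16L (1.18, adjusted p = 0.00109), TRIM16 (0.94, adjusted p = 0.00109), the growth inhibitor OSGIN1 (2.47, adjusted p = 0.00341) and NQO1 (0.67, from 196.2 to 313.0 CPM, adjusted p = 0.00341). Glutathione genes rose (4 of 27, 8 adjusted over the list alone, adjusted p = 5.45e-07, adjusted p = 0.101 with an estimated correlation), with GCLM at 1.38, glutathione reductase GSR at 0.64 and the transferase GSTM3 at 0.45. Selenoproteins, the class of GPX4 itself, were not called (2 of 20 higher, 3 adjusted over the list alone, adjusted p = 0.132), and the members that rose were thioredoxin reductase TXNRD1 (0.97) and the methionine sulfoxide reductase MSRB1 (0.38). Without BE(2) ML210 3 the selenoprotein list was called (0.0217). GCLM, GSR and TXNRD1 are also members of the NRF2 list.

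Among 24 ferroptosis suppressors, 5 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.00122, adjusted p = 0.101 with an estimated correlation). Those that rose were SLC7A11, GCLM, FTH1 (ferritin heavy chain, 1.16), the small heat shock protein HSPB1 (0.59) and AIFM2, which encodes the coenzyme Q reductase FSP1 (0.83, adjusted p = 0.0478). AIFM2 was not called without BE(2) control 1 (0.148), BE(2) control 2 (0.13), BE(2) control 3 (0.165), BE(2) ML210 1 (0.102) or BE(2) ML210 2 (0.162). DHCR7, the last enzyme of cholesterol synthesis, fell (-0.34). It is counted here only as a member of the list as fixed, and its role in ferroptosis was not tested. Among 23 ferroptosis promoters, 4 rose (4 up and 1 down adjusted over the list alone), namely HMOX1, the transferrin receptor TFRC (0.65), the P450 reductase POR (0.36) and CYB5R1 (0.91), and the list was not called (adjusted p = 0.292). Iron handling rose with 5 of 29 members (5 adjusted over the list alone, adjusted p = 0.00387, adjusted p = 0.101 with an estimated correlation). These were FTH1, FTL, HMOX1, TFRC and the heme transporter SLC48A1 (0.50, chosen after its value was seen). Of the genes in this paragraph, SLC7A11, GCLM, FTH1, FTL, HMOX1 and SLC48A1 are also members of the NRF2 list. The rises of these lists therefore rest in part on the same genes. SLC48A1 was not called without BE(2) control 2 (0.108), BE(2) control 3 (0.155), BE(2) ML210 1 (0.177) or BE(2) ML210 2 (0.166).

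Metallothioneins rose (2 of 8, 7 adjusted over the list alone, median 1.63, adjusted p = 1.24e-07, adjusted p = 0.101 with an estimated correlation), with MT1G at 6.33 and MT1H at 5.76 from levels of 0.334 and 0.0369 CPM. MT1H had 8 reads in the 3 controls, and its rise became 7.01 without BE(2) control 2, where it was not called (0.0649). It was not called either without BE(2) control 1 (0.123), BE(2) control 3 (0.123), BE(2) ML210 1 (0.08) or BE(2) ML210 2 (0.087). MT1G was called in only 1 of the 6 fits without 1 library, with a highest adjusted p of 0.117. Lysosome and autophagy genes rose (3 of 26, 15 adjusted over the list alone, median 0.30, adjusted p = 3.04e-12, adjusted p = 0.101 with an estimated correlation), with the autophagy receptor SQSTM1 at 1.22 and the sialidase NEU1 at 0.35. ATF4 targets rose (2 of 37; 15 up and 1 down adjusted over the list alone, median 0.25, adjusted p = 3.93e-08, adjusted p = 0.101 with an estimated correlation), with CEBPB at 0.48. The unfolded protein response rose (0 of 23, 5 adjusted over the list alone, adjusted p = 3.32e-05, adjusted p = 0.305 with an estimated correlation). The heat shock list rose (1 of 21, 8 adjusted over the list alone, adjusted p = 3.32e-05, adjusted p = 0.498 with an estimated correlation), with HSPB1 as its called member. Hypoxia targets rose (1 of 22, 2 adjusted over the list alone, adjusted p = 0.00556, adjusted p = 0.643 with an estimated correlation), with the neuronal enolase ENO2 at 0.47.

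Cholesterol synthesis genes fell (4 of 24, 14 adjusted over the list alone, median -0.21, adjusted p = 1.18e-11, adjusted p = 0.101 with an estimated correlation), with squalene epoxidase SQLE at -0.35, DHCR7 and the squalene synthase FDFT1 at -0.30. Proliferation genes fell (3 of 32, 16 adjusted over the list alone, median -0.19, adjusted p = 1.88e-13, adjusted p = 0.206 with an estimated correlation), namely topoisomerase TOP2A (-0.45), the thymidylate synthase TYMS (-0.38) and the ribonucleotide reductase RRM2 (-0.37). Adrenergic identity genes fell (2 of 25, 5 adjusted over the list alone, median -0.26, adjusted p = 3.32e-05, adjusted p = 0.470 with an estimated correlation), namely RET and the homeobox gene PHOX2A (-0.69). Fatty acid synthesis fell as a list (median -0.14, adjusted p = 0.0247, adjusted p = 0.506 with an estimated correlation, and 0.0736 without BE(2) control 1), with 1 up and 4 down adjusted over the list alone, while its only member called over all genes, the desaturase family gene FADS3, rose (0.78). Histones, the check on RNA selection, were called lower (median -0.19 but mean 0.02, adjusted p = 0.042, adjusted p = 0.596 with an estimated correlation, 1 down adjusted over the list alone). That call was lost with a prior count of 0.5 (0.0533), with a replicate block within each line (0.0927) or in this line alone (0.0837), and without BE(2) control 1 (0.0605), BE(2) control 2 (0.247), BE(2) ML210 1 (0.0641) or BE(2) ML210 2 (0.17).

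The lists not called in the libraries labelled SK-N-BE(2) included the mitochondrially encoded transcripts (adjusted p = 0.0529), which were called higher without BE(2) control 3 (0.0227), BE(2) ML210 1 (0.0254) or BE(2) ML210 3 (0.00232). Ribosomal proteins (0.557) were called without BE(2) control 1 (0.0354), BE(2) control 3 (0.0338) or BE(2) ML210 2 (0.0221), and NF-kB targets (0.88) without BE(2) ML210 2 (0.038). Among p53 targets PLK2 fell (-0.59) and the list was not called (0.496; median -0.01, mean 0.09; 1 up and 1 down adjusted over the list alone). The adjusted p was 0.412 for the mesenchymal list, 0.576 for endothelial markers, 0.808 for interferon-stimulated genes, 0.87 for Schwann cell markers (1 higher adjusted over the list alone), 0.88 for immediate early genes, 0.905 for both epithelial markers and the respiratory chain, and 0.928 for targets of MYC and MYCN.

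The 3 ML210 libraries labelled SK-N-BE(2) were far apart, with HMOX1 at 147.6, 58.24 and 23.47 CPM and SLC7A11 at 79.85, 37.93 and 22.63 CPM in replicates 1, 2 and 3. The count of 279 became 76, 117 and 79 without BE(2) control 1, 2 and 3, and 79, 48 and 1242 without BE(2) ML210 1, 2 and 3. It became 455 (272 higher, 183 lower) with a replicate block common to both lines and 1386 (695 higher, 691 lower) with a block within each line, of which 277 were among the 279. The common block ended the calls of KIF1A (adjusted p = 0.0672), SLC7A11 (0.0503) and TYMS (0.0546), and the block within each line that of KIF1A (0.0846). Of the 47 named genes, 9 were called in every fit without 1 library: RET, TIMP3, MYH15, TRIM16, TRIM16L, OSGIN1, NQO1, FTH1 and TXNRD1. The number of named genes that lost their call was 31, 28 and 31 without BE(2) control 1, 2 and 3, and 24, 38 and 0 without BE(2) ML210 1, 2 and 3. For HMOX1 the highest of these adjusted p was 0.119 and for SLC7A11 it was 0.147.

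The replicate block within each line also raised the counts of called members over all genes. It called 31 NRF2 targets, 12 lysosome genes, 11 ATF4 targets (and 1 lower), 9 ferroptosis suppressors (and 3 lower), 8 glutathione genes, 6 genes of the unfolded protein response, 5 heat shock genes, 4 metallothioneins and 4 hypoxia targets higher. Lower were 13 cholesterol synthesis genes, 11 adrenergic genes (and 1 higher), 9 fatty acid synthesis genes (and 2 higher) and 8 proliferation genes. Ferroptosis promoters had 5 higher and 2 lower, p53 targets 1 higher and 2 lower, and immediate early genes 1 higher and 2 lower. The mesenchymal and epithelial lists had 1 higher and 1 lower each, targets of MYC and MYCN 1 higher, and NF-kB targets, interferon-stimulated genes and endothelial markers 1 lower each.

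Other settings ended calls of named genes as well. With limma-voom these were HMOX1 (adjusted p = 0.118), SLC7A11 (0.101), TUBA4A (0.0995), B4GALNT1 (0.0626), PALM3 (0.102), RENBP (0.0744), CYB5R1 (0.0568), MT1G (0.403) and MT1H (0.373), all still higher with ML210. RLE factors ended those of PLK2 (0.0502), RRM2 (0.0531) and TYMS (0.0568), and library totals that of PLK2 (0.0501). In a fit of the 6 libraries labelled SK-N-BE(2) alone, 51 genes were called (15 higher, 36 lower), and 37 of the named genes lost their call, among them HMOX1 (0.178) and SLC7A11 (0.204). With a replicate block in that fit, 6 lost it: HMOX1 (0.151), SLC7A11 (0.157), B4GALNT1 (0.14), KIF1A (0.053), PALM3 (0.0755) and MT1G (0.073).

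**Figure D2:**
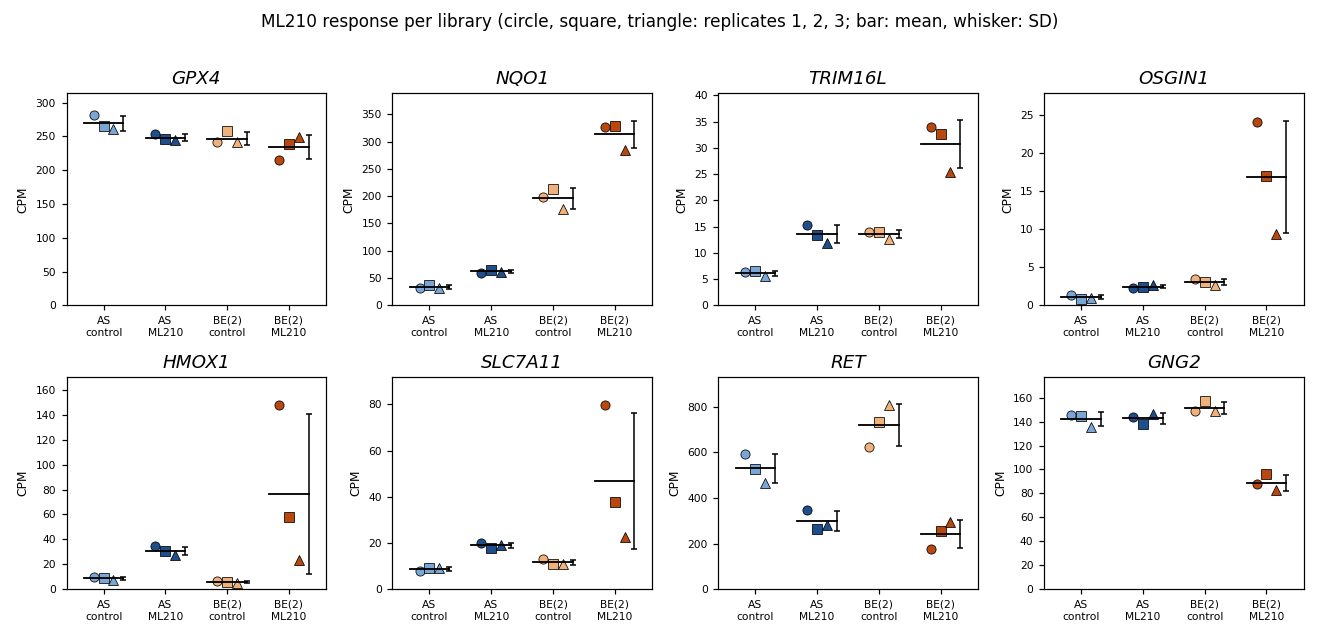
CPM of GPX4, the NRF2 targets NQO1, TRIM16L, OSGIN1, HMOX1 and SLC7A11, RET and GNG2 in each of the 12 libraries by line label and treatment, with replicates as symbols, means as bars and whiskers of 1 SD (n = 3). HMOX1 in ML210 libraries labelled SK-N-BE(2) spans 23.47 to 147.6 CPM, while GNG2 falls from 151.5 to 88.93 CPM in that label alone.

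In the fit without a batch term, the response to ML210 differed between the line labels in 1 gene. GNG2, a gamma subunit of heterotrimeric G proteins (ENSG00000186469, chromosome 14, 51826195 to 51979342), stood at 141.8 ± 5.9 CPM in controls and 142.7 ± 4.38 CPM with ML210 labelled SK-N-AS, and at 151.5 ± 4.91 and 88.93 ± 6.65 CPM labelled SK-N-BE(2). The log2 difference of its responses was -0.78 (SE 0.085, adjusted p = 0.00791), in the same direction in 3 of 3 batches and called in all 12 fits without 1 library. In the fit without a batch term none was called in the other direction, and 1454 genes had an unadjusted p under 0.05. DESeq2 called 45 genes, and the fit with a replicate block within each line called 85. The sign of each difference is the response labelled SK-N-BE(2) minus that labelled SK-N-AS, and MYCN contradicts those labels.

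As lists, NRF2 targets responded more in the libraries labelled SK-N-BE(2), by a median log2 of 0.39 (0 of 33 called, 15 adjusted over the list alone, adjusted p = 2.31e-09, adjusted p = 0.326 with an estimated correlation). Mitochondrially encoded transcripts, the check on RNA quality, differed by 0.51 (10 adjusted over the list alone, adjusted p = 1.42e-07, adjusted p = 0.326 with an estimated correlation) and lysosome genes by 0.18 (0 adjusted over the list alone, adjusted p = 1.43e-05, adjusted p = 0.326 with an estimated correlation). Glutathione genes differed by 0.13 (0 adjusted over the list alone, adjusted p = 0.00518, adjusted p = 0.326 with an estimated correlation). Cholesterol synthesis genes differed by -0.17 (1 adjusted over the list alone, adjusted p = 6.5e-06, adjusted p = 0.326 with an estimated correlation) and histones, the check on RNA selection, by -0.42 (0 adjusted over the list alone, adjusted p = 0.000282, adjusted p = 0.326 with an estimated correlation). These 6 of the 16 called lists were called in every fit without 1 library. In the ML210 libraries the mitochondrial share of reads was 2.52, 2.94 and 2.17% labelled SK-N-BE(2), beside 2.32, 2.11 and 2.46% in their controls.

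The other 10 called lists each lost their call without some library, and none of their members was called over all genes. Hypoxia targets (adjusted p = 0.000355) lost it without AS control 3 (0.0762), and heat shock (0.0011) and adrenergic genes (0.0011) without BE(2) ML210 1 (0.18 and 0.0867). With an estimated correlation the adjusted p of these 3 was 0.534 each. The respiratory chain (0.00526, adjusted p = 0.543 with an estimated correlation) lost it without AS control 3 (0.0762), BE(2) control 1 (0.187), BE(2) control 3 (0.102), BE(2) ML210 2 (0.16) or BE(2) ML210 3 (0.126). Selenoproteins (0.0116, adjusted p = 0.326 with an estimated correlation, 3 adjusted over the list alone) lost it without AS control 1 (0.0874), BE(2) control 3 (0.083) or BE(2) ML210 2 (0.0684). Immediate early genes (0.0142, adjusted p = 0.408 with an estimated correlation, 1 adjusted over the list alone) lost it without AS control 2 (0.0635) or AS ML210 2 (0.0955). Iron handling (0.022, adjusted p = 0.326 with an estimated correlation, 2 adjusted over the list alone) lost it with a replicate block within each line (0.0534) and without AS control 1 (0.0874), BE(2) control 2 (0.0576), BE(2) control 3 (0.0822) or BE(2) ML210 1 (0.0873).

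Ferroptosis suppressors (0.0263, adjusted p = 0.326 with an estimated correlation, 1 adjusted over the list alone) lost their call with that block (0.0534) and without AS control 3 (0.108), AS ML210 1 (0.0708), BE(2) control 2 (0.0576), BE(2) control 3 (0.0822) or BE(2) ML210 1 (0.127). Fatty acid synthesis (0.0263, adjusted p = 0.534 with an estimated correlation) lost it without AS control 1 (0.0937), AS ML210 2 (0.188) or BE(2) control 1 (0.092). Interferon-stimulated genes (0.0282, adjusted p = 0.326 with an estimated correlation) lost it without AS control 2 (0.129), AS ML210 2 (0.0892), BE(2) control 3 (0.076), BE(2) ML210 1 (0.0667) or BE(2) ML210 2 (0.0739). The adjusted p of the lists not called was 0.165 for proliferation, 0.186 for both ATF4 targets and the unfolded protein response, 0.219 for targets of MYC and MYCN, 0.284 for the mesenchymal list (0.0453 with the block within each line) and 0.367 for Schwann markers. It was 0.53 for ferroptosis promoters, 0.578 for metallothioneins (median below 0, mean 0.20; 1 lower adjusted over the list alone), 0.68 for p53 targets (median -0.02, mean 0.14), 0.692 for epithelial markers, 0.75 for endothelial markers and 0.948 for both ribosomal proteins and NF-kB targets. Some were called without 1 library. Proliferation was called without AS ML210 3 (0.0342), BE(2) control 3 (0.0109) or BE(2) ML210 3 (4.12e-05), and the mesenchymal list without AS control 1 (0.0479), AS ML210 3 (0.0127) or BE(2) ML210 3 (0.0455). ATF4 targets were called without AS ML210 1 (0.0218) or BE(2) ML210 3 (0.0357), and targets of MYC and MYCN without AS ML210 1 (0.0218).

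With a replicate block within each line, 85 genes differed in response (48 higher, 37 lower in the label SK-N-BE(2)), and without BE(2) ML210 3 the count was 156 (97 higher, 59 lower). Among the 85, chosen after their values were seen, TXNRD1 (0.68), FTH1 (0.84), the glucose transporter SLC2A1 (0.64) and the neurofilament genes NEFM (1.19) and NEFL (0.60) had a higher log2 change in the libraries labelled SK-N-BE(2). RET (-0.77), chromogranin CHGB (-0.82), the dopamine synthesis enzyme DDC (-0.58) and the tetrahydrobiopterin enzyme GCH1 (-0.48) had a lower one. By list, that block called 2 NRF2 targets, 2 selenoproteins, 1 hypoxia target, 1 iron handling gene and 1 ferroptosis suppressor higher (1 lower), and 3 adrenergic genes lower.

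The lines shared 5 called genes, all moving the same way: NQO1, TRIM16L, PIR and CPT1A rose and HR fell in both. Independent lists of these lengths would share 0.0409 rising genes (exact hypergeometric p = 2.14e-08 for 4) and 0.00557 falling genes (exact hypergeometric p = 0.00557 for 1). The comparisons have no library in common, but in 1 fit they share the estimate of spread of each gene, so the lists are not independent in that respect. With each line fitted alone, 4 rising genes were shared among 15 and 15 called (exact hypergeometric p = 6.14e-10). In those fits 1 falling gene was shared among 6 and 33 (exact hypergeometric p = 0.012). None was called in opposite directions. Across the 279 genes called in the libraries labelled SK-N-BE(2), 86.7% had the same sign in those labelled SK-N-AS (Pearson r = 0.759, Spearman rho = 0.732), with a median absolute log2 change of 0.519 against 0.152. Across 11022 genes with a mean log2 CPM of at least 2, 59.8% had the same sign, r was 0.355 and rho 0.279, and genes are not independent replicates. The shared count was 28 with a replicate block within each line, 3 without AS control 2, AS ML210 2, AS ML210 3, BE(2) control 2 or BE(2) ML210 2, and 11 without BE(2) ML210 3.

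**Figure D3:**
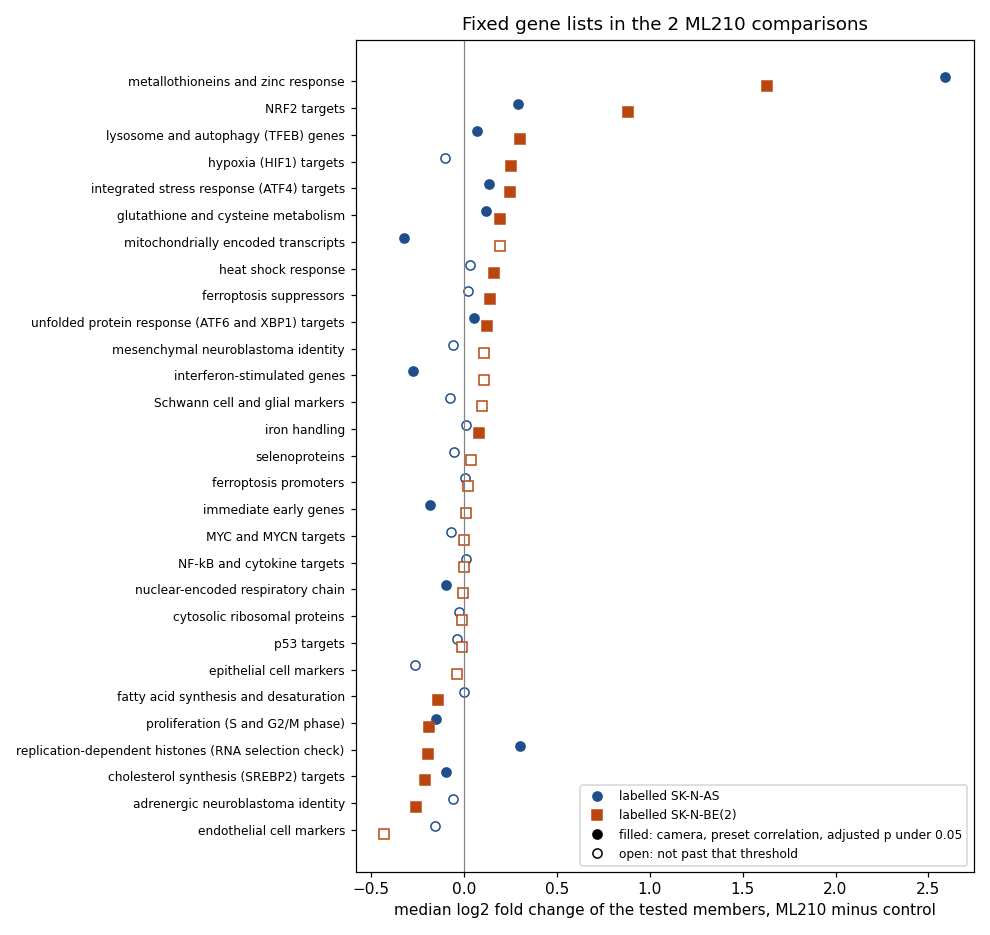
Median log2 fold change (ML210 minus control) of the tested members of 29 gene lists in the libraries labelled SK-N-AS (circles) and SK-N-BE(2) (squares), filled where camera at the preset correlation passed an adjusted p of 0.05. NRF2 targets lie at 0.29 and 0.88, and mitochondrially encoded transcripts at -0.33 and 0.19, where the latter is not called.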

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

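Of the tests in this part, the 2 on exchanged and on mixed lines, those on depth and on the size of the NRF2 response, and the 3 on controls, treatment strength by batch and RNA of untreated cells were chosen, in the form given, only after the result was seen. By a test of the difference itself in the fit without a batch term, the response to ML210 differed between the line labels for 1 gene. By camera at the preset correlation it differed for 16 gene lists. None of the 16 lists passed with an estimated correlation. The gene was GNG2 (log2 -0.78). The lists are given with their median log2 difference (labelled SK-N-BE(2) minus labelled SK-N-AS). They were mitochondrially encoded transcripts (0.514), NRF2 targets (0.388), interferon-stimulated genes (0.380), hypoxia targets (0.358), immediate early genes (0.199), heat shock (0.192), lysosome genes (0.180), glutathione genes (0.134), ferroptosis suppressors (0.125), selenoproteins (0.093), iron handling (0.085) and the respiratory chain (0.080). The lists with a negative difference were histones (-0.418), adrenergic genes (-0.286), cholesterol synthesis (-0.173) and fatty acid synthesis (-0.108). MYCN contradicts the labels that give these differences their sign.

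Other splits of the same libraries into groups of the same size show how far chance can be excluded. For genes differing in response, 14 of 60 splits gave a count of at least the real 1, with 4 as the highest other, and for lists 3 of 60 gave at least the real 16, with 17 as the highest other. The 7 other splits that part as many batch pairs reached the same highest values, 4 and 17. The split with 4 genes still called 118 genes for ML210 labelled SK-N-BE(2), and the split with 17 lists called 100. Both kept the real groups of that label apart and so held its real response, and their values do not show what chance alone gives. The splits therefore do not exclude chance for either count. These counts have no batch term, and with a replicate block within each line 85 genes differed in response. For genes shared by both lines, 1 of 60 splits, the real one, gave 5 and the highest other gave 0. Of the 59 other splits, 58 had no call in at least 1 line and could share none, and 7 parted as many batch pairs as the real one, so the splits that test this count are too few for a share under 0.05. That limit on which splits count was set after their values were seen. The remaining designs allow 10 splits, too few for a share under 0.05. There the real count and the highest other were 6 and 12 genes for ML210 labelled SK-N-AS (2 of 10 splits as large), 279 and 8 labelled SK-N-BE(2) (1 of 10), and 14047 and 0 for the controls (1 of 10). The split with 12 put AS control 1 and AS ML210 1, both of batch 1, together with AS ML210 2, and with a replicate block within each line the real count was 38. For lists they were 13 and 12 (1 of 10), 15 and 16 (3 of 10), and 10 and 10 (4 of 10), and the median other split gave 6, 8 and 8 lists. The highest among the 3 other splits that part as many batch pairs was 9, 12 and 8 lists, and 0 genes in each of these comparisons.

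MYCN went against the line labels. Single libraries mislabelled or mixed are argued against as the source, since the highest MYCN level labelled SK-N-BE(2) was 0.00694% of the lowest labelled SK-N-AS. That value says nothing about small amounts of RNA passing the other way. The 42 genes high in the label SK-N-BE(2) had medians of 1.69 and 1.48% in AS control 2 and 3 and of 1.19 and 1.77% in AS ML210 2 and 3. In AS control 1 and AS ML210 1 their medians were 0.346 and 0.362%. Small amounts of such RNA in replicates 2 and 3 labelled SK-N-AS stay open. An exchange of the line labels for all libraries is consistent with MYCN, which lay on the side of the other line in 12 of 12 libraries, and nothing in the sources used here settles it. A gained copy number around MYCN in the libraries labelled SK-N-AS stays open. The median log2 difference of its tested neighbours within 1 Mb was -0.58, above the bound of -1 set beforehand, but that bound could not decide with 3 tested neighbours (NBAS -0.58, DDX1 -1.12 and CYRIA 1.28, the last near the floor and not called) and a gain need not reach them. The rule was changed after this value was seen to ask for at least 5 neighbours, and no other biological explanation for the conflict was tested. A gain in the libraries labelled SK-N-AS would leave unexplained the low MYCN in every library labelled SK-N-BE(2), which the design calls MYCN-amplified.

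More genes were called for ML210 in the libraries labelled SK-N-BE(2) than in those labelled SK-N-AS, 279 against 6 in the shared fit but 51 against 21 with each line fitted alone. Deeper libraries are argued against by a mean read total 0.90 times that of the other label. A larger spread labelled SK-N-AS, averaged over genes, is argued against by a ratio of common dispersions of 0.961 (0.852 with batch in the model). That ratio does not cover single genes, and in the shared fit both labels had the same estimate of spread for each gene. Of the 21 genes called labelled SK-N-AS alone, 6 were called in the shared fit, against 41 of 51 labelled SK-N-BE(2). Whether spread in the libraries of the other label ended those calls was not tested. A larger NRF2 response in the line labelled SK-N-BE(2) may contribute, as 27 of 33 tested targets had the larger fold change there. It stays open because the list did not differ with an estimated correlation (adjusted p = 0.326). Line and MYCN status stay among the open biological explanations, untested and confounded with each other.

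The ML210 libraries labelled SK-N-BE(2) differed in the size of the response, with NRF2 medians of 1.08, 0.96 and 0.54 relative to the control means in replicates 1, 2 and 3 (controls 0.07, 0.03 and -0.12), and of 0.92, 0.69 and 0.62 against the control of the same batch. RNA of untreated cells mixed into replicate 3 stays open: among genes called without the batch 3 libraries, those that fell kept a median share of 0.341 of their batch 1 change and those that rose 0.259, a difference of 0.0822 (permutation p = 1e-04, with genes that are not independent), while a first form on genes called with batch 3 gave 0.274 and was replaced because such genes were selected for keeping their change. A difference between the controls of the batches stays open, since their range was 0.352 of that of the ML210 libraries but 0.777 in a first form without centring each gene, which was replaced because genes of unequal level then set the median. A treatment strength that differed by batch in both lines stays open as well: the median over NRF2 targets of the batch 1 minus batch 3 response labelled SK-N-AS was -0.04 (95% interval over genes -0.16 to 0.03), in a form that replaced a difference of medians after that was seen. That interval treats genes as independent and does not measure the spread between batches. Against the control of the same batch, the medians labelled SK-N-AS were 0.26, 0.29 and 0.33 in batches 1, 2 and 3. No biological explanation was tested, because replicates of a group share every label but batch. The share of reads in ribosomal RNA genes, mitochondrial ones included, was 0.241, 0.213 and 0.148% in ML210 replicates 1, 2 and 3 labelled SK-N-BE(2). In their controls it was 0.17, 0.173 and 0.183%, and a link to the size of the response was not tested.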

How the results depend on the processing

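Each line fitted alone with a replicate block, list counts with single lines, blocks or left-out libraries, and shared counts with a block within each line or with lines fitted alone were chosen only after the result was seen. Counts stayed within 1.5 times under RLE factors, library totals, a stricter filter and limma-voom. Genes called for ML210 labelled SK-N-AS, ML210 labelled SK-N-BE(2) and the difference numbered 52, 790 and 45 with DESeq2 (26 shared), 33, 556 and 24 with no filter on low counts, and 0, 0 and 0 by glmTreat against a fold of 1.5 (244, 436 and 366 with an unadjusted p under 0.05; 0 shared), which left 8696 between the controls. With a replicate block within each line they were 38, 1386 and 85 (28 shared), and with a common block labelled SK-N-BE(2) 455. Lines fitted alone gave 21 and 51, and with a block 222 and 1044 (92 shared). Lists called were 0, 0, 0 and 0 (the last for the controls) with an estimated correlation and 1, 9, 0 and 25 by fry. Leave-one-out ranges were 3 to 6, 48 to 1242, 1 to 156 and 13401 to 13541 genes (the last for the controls), 3 to 11 shared, and 9 to 15, 14 to 17, 11 to 18 and 10 lists. A lone group of 2 libraries was assumed to vary like the others. Among named genes 0 reversed under DESeq2, limma-voom, other scaling, blocks, single-line fits or left-out libraries (glmTreat, which called 0 for ML210, and other filters are not in these numbers), and values that lost their call numbered 14, 212, 0 and 2 against 98, 474, 54 and 1594 that stayed on their side (SK-N-AS, SK-N-BE(2), difference, controls). Beyond those given beside the results, replicate blocks in fits of all 12 libraries ended no other call of a named gene and changed no other list call. The cause of these changes was not tested. Library totals of 54047293 to 83481963 reads limit values near the floor, such as MYCN labelled SK-N-BE(2).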

Other observations

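The genes in this part were chosen only after their values were seen, and no test was added for them. In the libraries labelled SK-N-BE(2), ML210 raised the neuronal ubiquitin hydrolase UCHL1 from 276.7 to 495.5 CPM (log2 0.84, adjusted p = 0.00109). The microtubule protein tau, MAPT, rose by 0.87 (adjusted p = 0.0136). TFE3, a transcription factor of lysosomal genes, rose by 0.54 (adjusted p = 0.00433).

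HES1, a Notch target that represses neuronal genes, fell from 19.4 to 11.3 CPM in those libraries (log2 -0.78, adjusted p = 0.0107). The kinase PRKCH fell from 2.29 to 0.453 CPM (log2 -2.34, adjusted p = 0.00341). None of these 5 genes passed the test for ML210 in the libraries labelled SK-N-AS or for the difference of the responses.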
